A study of Mus musculus with 6 samples.

How the data were processed

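The samples were libraries of epidermal cells from mouse back skin at embryonic day 16.5, after doxycycline from embryonic day 14.5, in a control group and a K10-spastin group of 3 libraries each. Per the labels' protocols, fluorescent cells were sorted after dispase and trypsin with versene, DNA was digested after RNA extraction, and libraries followed the standard Illumina procedure. The deposited table holds FPKM, fragments scaled by gene length and library depth, as the authors computed it, with 1 column per library and 35275 Ensembl gene identifiers. CASAVA and TopHat2 are named in the submitters' processing notes without versions. The counter, genome build, gene annotation and strandedness are not given in the sources used here, so no genome coordinates are printed, and reads of genes that overlap, or that have near-identical copies, may be split between them. Symbols came from a table of gene names that matched 34490 identifiers and left 785 unmatched.

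FPKM does not state depth. Where fragments were counted whole, the value of 1 fragment in a gene is set by gene length and library depth, so depth was read from the commonest step over 14953 genes with 1 annotated transcript, with exon lengths from GENCODE release M21, which may not be the annotation used for the table. With that depth, 90.7% to 91.6% of the low values, up to 20 fragments, were whole within 0.05. These depths, 16.0 to 22.5 M (mega) fragments, describe precision only. The values are FPKM and not counts, so the planned limma test on the log scale was used and no count test was run.

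Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 11071 in all, on log2(FPKM + 1), which understates the change of low genes. limma 3.58.1 in R 4.3.3 compared the groups with lmFit and eBayes with a trend, two-sided, with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. No covariate was used. The replicate number was not used as a block, since the labels do not say that it marks a shared litter or day. An exact permutation test of 3 against 3 cannot give a two-sided p below 0.1, so the printed p-values rest on limma's pooled variance. On data simulated from these libraries with 10823 genes, 52% of genes changed 2-fold and 98% of genes changed 4-fold were called, 5.06% of calls were on unchanged genes, and no call had the wrong sign. The simulated noise was independent between genes and had the same SD in both groups. The changed genes left out the lowest and highest levels. These rates therefore do not cover shared deviations, a larger spread in K10-spastin or low genes.

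The genes named were set by a rule before the data were examined. Spast came first. Then came the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap, leaving out predicted genes and pseudogenes. For each gene list up to 4 members could be named, the 2 with the smallest p and the 2 with the highest mean. Not all of the list members that the rule names are reported here. A gene outside the rule is said to have been chosen after its values were seen. The 41 lists were written before the data were examined from textbook knowledge of epidermis, cytoskeleton, signalling, stress, metabolism and the other cells that a sort of skin could hold. The 38 lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. An estimated correlation and fry were alternatives. In a list, a member rose or fell when it passed over all genes tested, and the count adjusted over the list alone is given beside it. On simulated data, a list of 20 genes raised 2-fold gave a camera p of 1.47e-33 and 1% of unchanged lists of independent genes had a p under 0.05.

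Alternatives covered pseudocounts of 0.1 and 0.5, no filter and a filter at 5 FPKM, median-of-ratios and quantile scaling, limma without a trend, with robust variances and with array weights, the replicate block, a fold of at least 2, and each library left out. Leaving out control 1 and K10-spastin 1 together was added after the data were seen. Copies of a transcript were found with BLAST 2.17.0 at an identity of at least 90% over at least 200 bases. Other scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.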

Results

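The experiment measured messenger RNA in differentiated cells of the embryonic mouse epidermis after the microtubule-severing enzyme spastin had been switched on in them. In K10-spastin embryos the keratin 10 promoter, active in the suprabasal layers that have left the basal layer, drives a doxycycline-dependent activator that turns on both a nuclear green fluorescent protein and spastin. Doxycycline was given from E14.5, back skin was taken at E16.5 (days of gestation), the epidermis was freed from the dermis with dispase, and fluorescent cells were sorted. There were 3 control and 3 K10-spastin libraries, each from an independent RNA sample per the labels. Which of the transgenes the control embryos carried is not given in the sources used here, so differences are between the groups as labelled and cannot be assigned to spastin apart from the other transgenes. How many embryos went into each library is not given in the sources used here, so p-values measure the spread between these samples. The step size of the low values gave depths of 22.5, 16.0 and 16.6 M (mega) fragments for controls 1 to 3, and of 17.4, 19.6 and 17.4 M for K10-spastin 1 to 3. In a transcript of 1 kb, 3 fragments were worth 0.133 to 0.187 FPKM, so levels below that were near the limit of detection. Between 10342 and 11190 genes per library reached 1 FPKM.

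The first principal component held 62.1% of the variance and separated the groups, and the second held 16%. Across genes, Pearson correlations of log2 values were 0.965 to 0.990 between control libraries, 0.943 to 0.968 between K10-spastin libraries and 0.863 to 0.936 between groups. K10-spastin 1 lay farthest from the controls, at 62.5 on the first component, against 31.5 and 24.3 for K10-spastin 2 and 3.

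Spast itself (ENSMUSG00000024068), the induced gene, was read first as a check of the labels. It stood at 21.2, 24.0 and 21.4 FPKM in controls 1 to 3 and at 1431, 639 and 213 FPKM in K10-spastin 1 to 3. The log2 change was 4.65 ± 0.60 (SE), with a limma adjusted p of 0.00865. Log2 changes here and below are on the log2(FPKM + 1) scale, which understates the change of low genes, and are given with their SE. The 3 K10-spastin libraries differed from each other in Spast by more than the controls did. The table has a single value per gene, so transcripts of the transgene and of the mouse gene are counted together.

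The main comparison asks how transcript levels differ in suprabasal cells in which spastin is induced. Of 11071 genes tested, 569 were higher and 653 lower in K10-spastin at a limma adjusted p under 0.05, and 394 and 423 of these changed at least 2-fold. Among the 10 largest rises on this scale were 2 keratins of wounded and hyperproliferative epidermis. Krt6b (ENSMUSG00000023041) went from 1.87 ± 0.898 to 1183 ± 1392 FPKM (SD, n = 3), with a log2 change of 8.02 ± 0.77 (adjusted p = 0.00435), and Krt6a (ENSMUSG00000058354) went from 8.12 ± 6.19 to 2201 ± 2234 FPKM (SD, n = 3), with a log2 change of 7.74 ± 0.87 (adjusted p = 0.00557). Klk6, a secreted kallikrein protease, went from 0.258 ± 0.136 to 289.9 ± 131 FPKM (SD, n = 3), with a log2 change of 7.77 ± 0.29 (adjusted p = 9.14e-05). Tslp, a cytokine that epithelia release to start allergic inflammation, went from 0.30 ± 0.0924 to 305 ± 256 FPKM (SD, n = 3), with a log2 change of 7.32 ± 0.78 (adjusted p = 0.00514). Among small proline-rich proteins of the cornified envelope, Sprr2h rose by 6.41 ± 0.63, Sprr1a by 5.85 ± 1.07 and Sprr1b by 5.71 ± 0.73 on the log2 scale. Sprr4 was listed at 0 in each control and at 141, 101 and 114 FPKM in K10-spastin 1 to 3. The water and glycerol channel Aqp9 rose by 5.47 ± 0.41 and the late envelope gene Lce1f by 5.46 ± 0.88.

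The largest falls were in a different set. Adh1 (ENSMUSG00000074207), an alcohol dehydrogenase that oxidises retinol, went from 227 ± 32.0 to 15.5 ± 18.9 FPKM (SD, n = 3), with a log2 change of -4.43 ± 0.72 (adjusted p = 0.0154). Fosb, an immediate-early transcription factor, went from 668 ± 212 to 60.9 ± 39.9 FPKM (SD, n = 3), with a log2 change of -3.57 ± 0.43 (adjusted p = 0.00712). Krt15, a keratin of basal cells, went from 1723 ± 439.7 to 260.2 ± 189.7 FPKM (SD, n = 3), with a log2 change of -3.05 ± 0.62 (adjusted p = 0.0269). The aldehyde dehydrogenase Aldh1a7 changed by -3.50 ± 0.50, the matrix glycoprotein Thbs1 by -3.45 ± 0.72, Egr4 by -3.39 ± 0.85, the actin-associated Pdlim4 by -3.18 ± 0.52 and the transcription factor Klf2 by -3.15 ± 0.63. The controls differed in 2 of these genes, with control 1 the lowest. Thbs1 stood at 9.28, 42.3 and 78.8 FPKM in controls 1 to 3 and at 0.921, 3.69 and 2.02 FPKM in K10-spastin 1 to 3. Egr4 stood at 5.51, 40.3 and 59.1 FPKM in the controls and at 0.377, 1.12 and 3.80 FPKM in K10-spastin. Egr4 (limma adjusted p = 0.0462) was not called in 9 of 16 other settings, both scalings among them (up to 0.147). Aldh1a7, Thbs1, Pdlim4 and Klf2 were not called without control 2 or without control 3. Hs3st6, a heparan sulfate sulfotransferase, changed by -3.13 ± 0.28 and the carnitine-family transporter Slc22a4 by -2.90 ± 0.35. In each of the 1222 genes called, the 3 libraries of one group lay entirely above those of the other. Such separation was found in 40.4% of all tested genes, against 10% by chance for 3 against 3. The counts were lower without any one of the controls. Without control 3 there were 113 higher and 32 lower genes, without control 2 there were 142 and 70, and without control 1 there were 219 and 230. Without K10-spastin 2 there were 360 and 344, but without K10-spastin 1 there were 691 and 691, and without K10-spastin 3 there were 665 and 701. Each of these fits had fewer libraries. A call lost here or below may reflect that smaller number and does not by itself show dependence on the library left out. Of 90 called genes named in the text, 36 were called without any one library, Spast, Krt6b, Krt6a, Klk6, Tslp and Fosb among them. Without control 1, 2 and 3 in turn, 39, 47 and 54 were no longer called, Adh1 (adjusted p up to 0.0625) and Krt15 (up to 0.0992) each time, and without K10-spastin 2, 26 were not. Counts of 319 and 348 with no filter, and of 1535 and 1771 with array weights, show that the counts of members below also depend on the filter and on the weight given to each library.

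**Figure D1:**
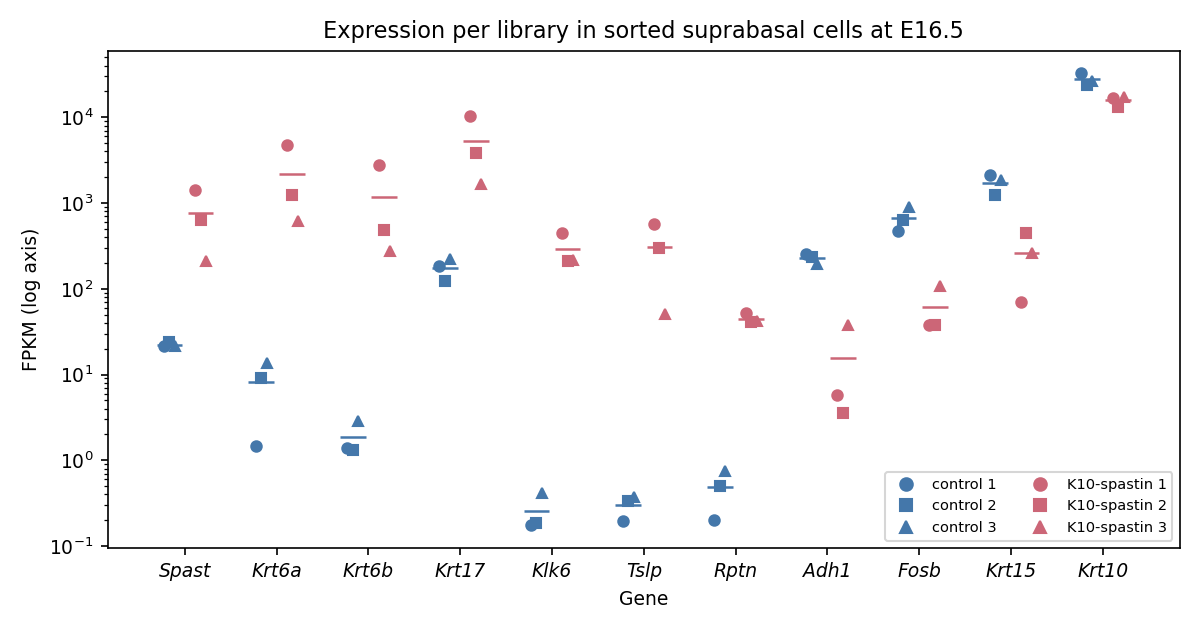
FPKM on a log axis for 11 genes in each of the 3 control (blue) and 3 K10-spastin (red) libraries, with bars at the group means. Spast, Krt6a, Krt6b, Krt17, Klk6, Tslp and Rptn lay higher in every K10-spastin library than in any control, and Adh1, Fosb, Krt15 and Krt10 lower.

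Gene groups were fixed before the data were examined, as 41 lists of which 38 had at least 3 tested members. By camera with a preset correlation, 9 lists were higher and 4 lower. With a correlation estimated from these libraries no list was called, with a smallest adjusted p of 0.336. The rotation test fry called the tubulin list (fry adjusted p = 8.24e-04) and the cholesterol synthesis list (0.00534). It did not call the other 11 of the 13 lists (adjusted p 0.0603 to 0.648). Ranges of list p-values below are of camera with the preset correlation. Other ways of splitting the same 6 libraries called between 9 and 22 lists. Each of them had libraries of both groups on both sides and kept part of the group difference, so these counts do not measure chance. Since the list tests differed, the counts of members that passed the limma test are given first for each group.

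Stress and wound genes formed the group with the largest changes. Of 17 tested stress keratins and alarmins, 10 rose (14 adjusted over the list alone; camera adjusted p = 4.77e-11, adjusted p = 0.623 with an estimated correlation, and 1.40e-14 to 3.63e-07 under 15 other settings). Besides Krt6b, Sprr2h and Sprr1a, Krt17 went from 177 ± 50.5 to 5330.0 ± 4595 FPKM (SD, n = 3), with a log2 change of 4.56 ± 0.61 (adjusted p = 0.00955). Of 31 tested genes of the granular layer and cornified envelope, 11 rose (21 adjusted over the list alone; camera adjusted p = 1.86e-10, adjusted p = 0.623 with an estimated correlation, and 5.74e-13 to 2.67e-07 under 15 other settings). Rptn, an envelope protein, went from 0.486 ± 0.277 to 44.9 ± 6.06 FPKM (SD, n = 3), with a log2 change of 4.96 ± 0.21 (adjusted p = 1.23e-04). Klk7, a protease that sheds corneocytes, rose by 5.2 ± 0.49, and the protease Asprv1, which processes filaggrin, rose by 2.34 ± 0.27. Lor, the main protein of the mature envelope, stood at 3667 ± 2152 FPKM in control and 6780.3 ± 6739.9 FPKM in K10-spastin (SD, n = 3; adjusted p = 0.583). Of 17 genes on the barrier lipid list, 4 rose, and 7 adjusted over the list alone (camera adjusted p = 3.76e-06, adjusted p = 0.655 with an estimated correlation, and 2.75e-10 to 0.00901 under 15 other settings). Pnpla1, needed for acylceramide, rose by 1.3 ± 0.16. The largest rise on the list, 2.95 ± 0.54, was that of Spink5, a protease inhibitor and not a lipid gene. The count and the list p-values thus rest in part on a gene outside lipid synthesis. The fatty acid elongases Elovl4 and Elovl1 had changes of 0.42 ± 0.26 and 0.42 ± 0.27 (adjusted p = 0.310 and 0.326). Without control 1, 2 and 3 in turn, 9, 6 and 5 stress genes, 7, 9 and 5 envelope genes, and 1, 1 and 1 genes of the barrier lipid list rose. Without K10-spastin 1, 21 envelope genes rose, and under quantile normalization 1 fell.

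Markers of the spinous layer did not rise with these groups. Of 16 tested spinous genes, 1 fell and no member passed adjusted over the list alone (camera adjusted p = 0.948). The member that fell was Krt10, whose promoter drives the transgene, which went from 27671 ± 4471 to 15789.9 ± 2358 FPKM (SD, n = 3), with a log2 change of -0.81 ± 0.20 (adjusted p = 0.0438). Its partner Krt1 and Skint6 had changes of -0.69 ± 0.22 and -1.24 ± 0.33 (adjusted p = 0.0838 and 0.0561). Over 16 other settings the adjusted p of Krt10 ranged from 0.0178 to 0.783, and 9 of them ended the call. These were each control left out, K10-spastin 2 or 3 left out, control 1 and K10-spastin 1 left out together, median-of-ratios scaling, no filter, and quantile normalization, where the change was -0.07. Krt1 and Krt10 together held 3.74% to 9.59% of all FPKM in a library. Quantile normalization gives equal ranks equal values, so it can remove a change in so abundant a gene by construction. Of 16 differentiation transcription factors, 4 rose (4 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0685, and 0.0248 to 0.404 under 15 other settings, 5 of which called it higher). Ehf rose by 2.79 ± 0.29 and Hopx by 3.08 ± 0.54, while Cebpa and Klf4 had changes of 0.26 ± 0.13 and -0.04 ± 0.16 (adjusted p = 0.227 and 0.906). The factors that rose numbered 2 without control 1, control 2, K10-spastin 1 or K10-spastin 2, and 1 without control 3. Under quantile normalization 2 rose and 2 fell, and under median-of-ratios scaling 2 rose and 1 fell. The settings among those 15 that called the list were no filter and the removal of control 2, control 3, K10-spastin 2 or K10-spastin 3. The replicate block, outside those 15, also called it.

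The cytoskeleton that spastin acts on also differed at the transcript level. Of 14 tested tubulin genes, 7 rose (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.96e-05, adjusted p = 0.336 with an estimated correlation, and 9.37e-06 to 6.80e-04 under 15 other settings). Tuba8 went from 4.94 ± 1.98 to 95.6 ± 53.4 FPKM (SD, n = 3), with a log2 change of 3.96 ± 0.41 (adjusted p = 0.00480). Tubb2b went from 2.81 ± 0.711 to 61.8 ± 46.8 FPKM (SD, n = 3), with a log2 change of 3.81 ± 0.48 (adjusted p = 0.00799). Tuba4a, abundant in both groups, went from 355 ± 14.7 to 743 ± 261 FPKM (SD, n = 3), with a log2 change of 1.01 ± 0.23 (adjusted p = 0.0352). Tuba4a was not called under median-of-ratios or quantile scaling, with no filter, or without any one of the controls (limma adjusted p up to 0.124). Tubb4b, also abundant, had a change of 0.22 ± 0.11 (adjusted p = 0.225). Of 26 microtubule regulators, 4 rose and 2 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.377). The severing protein Katnal1 changed by -1.38 ± 0.20 and the centrosomal anchor Nin by -2.07 ± 0.38, both lower, and Map7d1, which stabilises microtubules, by 1.86 ± 0.40. The tubulin cofactor Tbca had a change of 0.16 ± 0.13 (adjusted p = 0.438). The tubulins that rose numbered 4, 3 and 2 without control 1, 2 and 3 in turn, and 5 rose and 1 fell under median-of-ratios scaling. The regulators that rose and fell numbered 0 and 1 without control 1, 0 and 0 without control 2 or control 3, 5 and 5 without K10-spastin 1, and 2 and 1 without K10-spastin 2. Scaling turned the balance of the regulators, with 3 that rose and 5 that fell under quantile normalization and 2 and 3 under median-of-ratios scaling.

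Of 27 actomyosin genes, 6 rose (8 adjusted over the list alone; camera adjusted p = 4.60e-06, adjusted p = 0.655 with an estimated correlation, and 6.43e-08 to 0.0244 under 15 other settings). Myh14, a nonmuscle myosin heavy chain, went from 5.04 ± 1.33 to 64.9 ± 27.6 FPKM (SD, n = 3), with a log2 change of 3.39 ± 0.30 (adjusted p = 0.00391). The tropomyosin Tpm2 went from 4.15 ± 2.01 to 62.9 ± 30.2 FPKM (SD, n = 3), with a log2 change of 3.56 ± 0.46 (adjusted p = 0.00876). The abundant actins Actg1 and Actb had changes of 0.37 ± 0.25 and -0.11 ± 0.22 (adjusted p = 0.356 and 0.770). Of 17 targets of the actin-sensing factors SRF and MRTF, 2 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.130, and 0.0157 to 0.897 under 15 other settings, 3 of which called it higher). Fhl2 rose by 2.31 ± 0.41 and Pdlim7 by 1.94 ± 0.39, and Flna had a change of 0.42 ± 0.25 (adjusted p = 0.287). Of 18 targets of the mechanically regulated factors YAP and TAZ, 1 rose and 1 fell, with the same counts adjusted over the list alone. The median change of that list was 0.10, its mean was -0.02, and camera gave an upward direction (adjusted p = 0.540). Ccn2 rose by 1.43 ± 0.34 and Igfbp3 changed by -1.72 ± 0.19, and Ccn1, which is also on the SRF list, had a change of -1.12 ± 0.51 (adjusted p = 0.178). The actomyosin genes that rose numbered 4, 3 and 3 without control 1, 2 and 3 in turn, 4 without K10-spastin 1 and 3 without K10-spastin 2. No SRF or MRTF target rose without any one of the controls, and 1 rose without K10-spastin 2. Without control 1 and K10-spastin 1 together, no SRF or MRTF target rose and 2 fell. The targets that rose under median-of-ratios scaling numbered 4 for SRF and MRTF and 2 for YAP and TAZ. No YAP or TAZ target rose without any one of the controls or K10-spastin 2, and 3 fell without control 1.

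Genes of cell contacts moved both ways. Of 16 desmosome genes, 2 rose and 1 fell (2 and 2 adjusted over the list alone). The list had a median of -0.13, a mean of 0.16 and an upward camera direction (adjusted p = 0.612). The desmosomal cadherin Dsg3 rose by 1.38 ± 0.26 and Dsc3 changed by -0.78 ± 0.11, with Jup and Perp at 0.31 ± 0.14 and -0.05 ± 0.17 (adjusted p = 0.190 and 0.871). Of 19 adherens and tight junction genes, 2 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.060, and 0.00695 to 0.752 under 15 other settings, 4 of which called it higher). Tjp3 changed by -1.20 ± 0.22, while Cdh1 had a change of 0.25 ± 0.17 (adjusted p = 0.35). Of 14 integrin and matrix genes of keratinocytes, 1 rose and 2 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.574). Itgav rose by 1.13 ± 0.22 and Itgb5 changed by -0.78 ± 0.15. Without control 2 or without control 3, no member of these 3 lists passed. Without control 1, 1 desmosome gene and 1 integrin gene fell and no other member passed, and without K10-spastin 2 the members that rose numbered 0, 1 and 0. Without K10-spastin 3, 5 junction genes and 2 integrin genes rose. Quantile normalization gave 2 and 2 for desmosome genes and 1 and 2 for junction genes, which had 1 and 1 under median-of-ratios scaling. The junction list was called with no filter or without control 2, control 3 or K10-spastin 3. It was also called with the replicate block, which is outside the 15 settings.

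Cholesterol synthesis was, of the 38 lists tested, the one in which the largest share of members rose. Of 20 tested genes, 16 rose (18 adjusted over the list alone; camera adjusted p = 3.05e-15, adjusted p = 0.439 with an estimated correlation, and 2.78e-20 to 4.12e-10 under 15 other settings). Mvd, of the mevalonate pathway, went from 16.3 ± 1.00 to 63.5 ± 7.70 FPKM (SD, n = 3), with a log2 change of 1.89 ± 0.14 (adjusted p = 0.00318). Fdft1, the squalene synthase, went from 15.3 ± 0.627 to 48.3 ± 1.87 FPKM (SD, n = 3), with a log2 change of 1.60 ± 0.13 (adjusted p = 0.00318). Fdps went from 110.3 ± 6.72 to 304 ± 44.3 FPKM (SD, n = 3), with a log2 change of 1.45 ± 0.14 (adjusted p = 0.00418), and Idi1 went from 72.8 ± 13 to 192 ± 25.7 FPKM (SD, n = 3), with a log2 change of 1.40 ± 0.17 (adjusted p = 0.00736). Leaving out control 2 or control 3 left 9 of these genes higher. Of 22 glycolysis and hypoxia genes, 3 rose (9 adjusted over the list alone; camera adjusted p = 1.38e-05, adjusted p = 0.655 with an estimated correlation, and 3.76e-08 to 0.0303 under 15 other settings). Egln3 rose by 1.5 ± 0.28, Pfkp by 1.43 ± 0.35 and Ldha by 0.47 ± 0.12, and Gapdh had a change of 0.52 ± 0.15 (adjusted p = 0.0641). No member of the glycolysis list rose when any of the controls, or K10-spastin 2, was left out, and 7 rose without K10-spastin 3. Without control 1 and K10-spastin 1 together, none rose and 2 fell.

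Ribosomal protein genes lay slightly lower in K10-spastin. No member of 32 passed the limma test, over all genes or adjusted over the list alone, with 12 lower at an unadjusted p under 0.05. The list median was -0.29 against -0.09 for all tested genes (camera adjusted p = 4.60e-05, adjusted p = 0.659 with an estimated correlation, and 9.33e-06 to 6.28e-04 under 15 other settings). Rps19 and Rplp0 had changes of -0.61 ± 0.16 and -0.58 ± 0.17 (adjusted p = 0.0558 and 0.0733). Without K10-spastin 1, 2 ribosomal protein genes fell, as under median-of-ratios or quantile scaling, and 12 fell with array weights. Of 24 nuclear genes of oxidative phosphorylation, 1 rose, also adjusted over the list alone. The list had a median of -0.01, a mean of 0.04 and an upward camera direction (adjusted p = 0.346, and 0.0142 to 0.859 under 15 other settings, 2 of which called it higher). That gene was Ndufa4, which went from 91.3 ± 5.18 to 195 ± 7.45 FPKM (SD, n = 3), with a log2 change of 1.09 ± 0.11 (adjusted p = 0.00469), and 2 rose under median-of-ratios scaling. None of 12 mitochondrially encoded genes passed by limma, including at an unadjusted p under 0.05 (camera adjusted p = 0.303, and 0.0191 to 0.969 under 15 other settings, 1 of which called it higher), and mt-Co1 had a change of 0.16 ± 0.25 (adjusted p = 0.713).

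**Figure D2:**
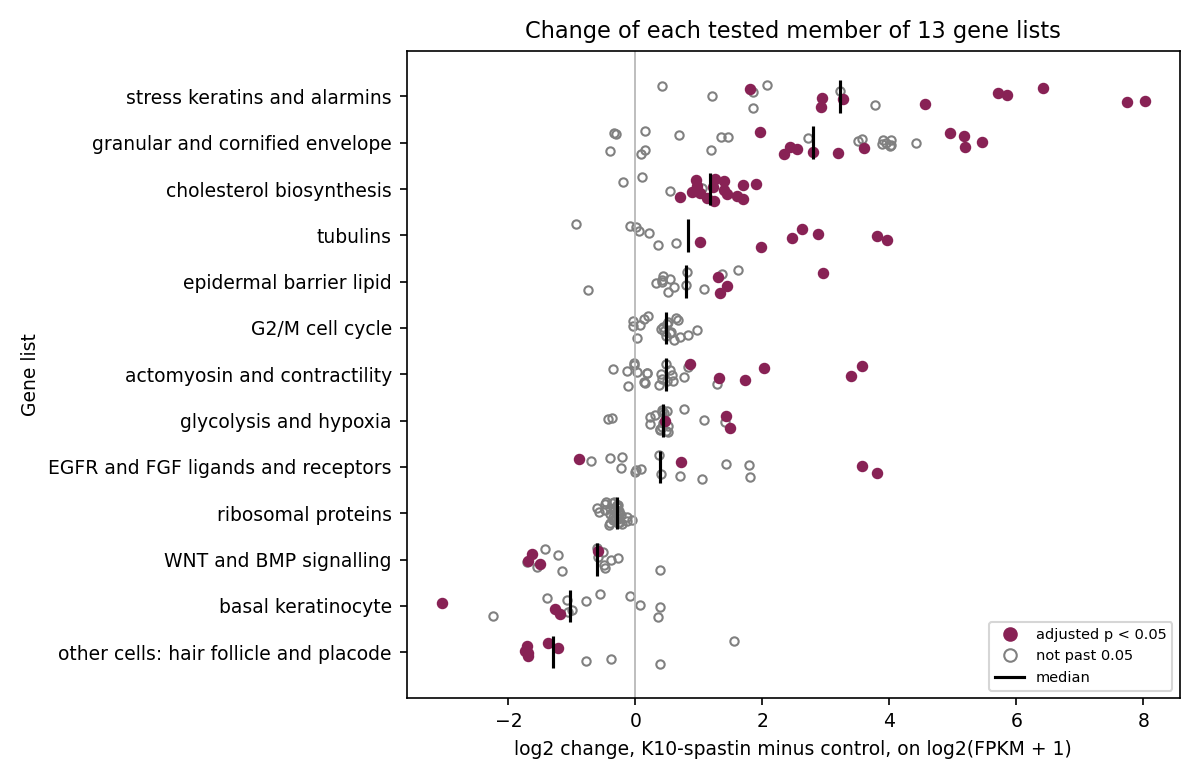
The log2 change between K10-spastin and control of each tested member of the 13 gene lists that camera called with a preset correlation, with filled points past an adjusted p of 0.05 and bars at list medians. In cholesterol synthesis 16 of 20 members are filled, against none of 32 ribosomal protein genes.

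Cell cycle genes varied between the K10-spastin libraries. None of 20 tested G2/M genes passed by limma, with 1 higher at an unadjusted p under 0.05, though camera called the list higher (adjusted p = 0.0202, adjusted p = 0.746 with an estimated correlation, and 5.99e-10 to 0.237 under 15 other settings, 3 of which ended the call). The list median against the control mean was -0.53 in K10-spastin 1, 1.22 in K10-spastin 2 and 0.72 in K10-spastin 3, while controls lay between -0.04 and 0.04. Without K10-spastin 1, 15 G2/M genes rose and 1 S phase gene rose, and with array weights 13 and 3 did. Without control 1 and K10-spastin 1 together, an alternative chosen after the data were seen, 11 G2/M genes rose. Cdc20 and Bub1b had changes of 0.98 ± 0.40 and 0.82 ± 0.49 (adjusted p = 0.144 and 0.292). None of 18 S phase genes passed by limma, including at an unadjusted p under 0.05 (camera adjusted p = 0.259, and 0.00190 to 0.868 under 15 other settings, 2 of which called it higher). Mcm3 had a change of 0.64 ± 0.33 (adjusted p = 0.228) and Pcna of -0.21 ± 0.27 (adjusted p = 0.64).

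Of 18 ligands, receptors and effectors of EGFR and FGF signalling, 3 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0240, adjusted p = 0.655 with an estimated correlation, and 0.00236 to 0.789 under 15 other settings, 7 of which ended the call). Etv4, a factor downstream of FGF receptors, went from 3.96 ± 1.44 to 61.0 ± 31.4 FPKM (SD, n = 3), with a log2 change of 3.56 ± 0.37 (adjusted p = 0.00480). Fgfbp1 rose by 0.72 ± 0.15 and Fgfr3 changed by -0.88 ± 0.14, and Erbb2 had a change of -0.01 ± 0.15 (adjusted p = 0.982). Of 17 WNT and BMP genes, 4 fell (6 adjusted over the list alone; camera adjusted p = 0.00140, adjusted p = 0.655 with an estimated correlation, and 1.44e-04 to 0.0138 under 15 other settings). Wnt10b went from 20.7 ± 7.36 to 5.84 ± 1.54 FPKM (SD, n = 3), with a log2 change of -1.63 ± 0.30 (adjusted p = 0.0195), and Id2, a BMP target, went from 3.92 ± 0.775 to 0.796 ± 0.577 FPKM (SD, n = 3), with a log2 change of -1.5 ± 0.30 (adjusted p = 0.0254). Wnt7b and Id3 had changes of -0.61 ± 0.19 and -1.71 ± 0.74 (adjusted p = 0.0819 and 0.161). Of 10 Notch pathway genes, 1 fell (3 adjusted over the list alone; camera adjusted p = 0.220). That gene was Maml2, with a change of -1.29 ± 0.30, and Hes1 had a change of -1.36 ± 0.53 (adjusted p = 0.130). The WNT and BMP genes that fell numbered 0, 1 and 0 without control 1, 2 and 3 in turn, and 2 without K10-spastin 1. No Notch pathway gene fell without control 2 or control 3. The EGFR and FGF genes that rose numbered 1 without control 2, control 3 or K10-spastin 2, and Fgfr3 was not called without control 2 or control 3 (adjusted p up to 0.0606). Under median-of-ratios scaling 5 of these genes rose, and without control 1 and K10-spastin 1 together 2 rose and 3 fell.

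Of 17 cytokine and chemokine genes, 4 rose (5 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0733, and 0.00291 to 0.904 under 15 other settings, 4 of which called it higher). Il18 went from 0.576 ± 0.448 to 41.4 ± 29.3 FPKM (SD, n = 3), with a log2 change of 4.54 ± 0.52 (adjusted p = 0.00600), beside Tslp. Nfkbia had a change of -0.35 ± 0.41 (adjusted p = 0.608). Of 8 interferon response genes, 1 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.281). These were Bst2, which rose by 0.79 ± 0.18, and Ifi35, which changed by -1.20 ± 0.29. Of 16 targets of p53, 1 rose and 3 fell (1 and 7 adjusted over the list alone; camera adjusted p = 0.224, and 0.00868 to 0.553 under 15 other settings, 2 of which called it lower). Phlda3 rose by 1.69 ± 0.28, Trp53inp1 changed by -2.06 ± 0.30, and Cdkn1a had a change of 0.11 ± 0.20 (adjusted p = 0.751). Of 20 genes of the integrated stress and unfolded protein responses, 3 rose and 2 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.0685, and 0.0175 to 0.258 under 15 other settings, 4 of which called it higher). Trib3 rose by 2.12 ± 0.29 and Chac1 by 1.33 ± 0.21, Atf3 changed by -2.33 ± 0.50, and Hspa5 had a change of 0.28 ± 0.17 (adjusted p = 0.308). The stress response genes that rose and fell numbered 1 and 0 without control 2, 0 and 0 without control 3, 5 and 0 without K10-spastin 1, and 3 and 0 without K10-spastin 2. Under median-of-ratios scaling 6 rose and 1 fell, and that setting called the list higher, as did no filter and the removal of control 2 or K10-spastin 1. The p53 list was called lower without control 1, and without control 1 and K10-spastin 1 together. The cytokine list was called with no filter or without control 2, control 3 or K10-spastin 3. It was also called with the replicate block, which is outside the 15 settings. No p53 target passed without control 2 or control 3, and 1 fell without K10-spastin 1 or K10-spastin 2. No interferon response gene passed without any one of the controls or K10-spastin 2, and 2 cytokine and chemokine genes rose without any one of the controls. Of 17 targets of the oxidative stress factor NRF2, 2 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.406). Srxn1 rose by 2.74 ± 0.28 and Nqo1 by 1.24 ± 0.19, and Taldo1 had a change of 0.02 ± 0.11 (adjusted p = 0.933). The NRF2 targets that rose numbered 1 without control 2 or control 3, where Nqo1 was no longer called, and 3 without K10-spastin 3. None fell under median-of-ratios scaling or without any one of the controls, K10-spastin 1 or K10-spastin 2, and 2 fell without K10-spastin 3.

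Of 23 immediate-early and heat shock genes, which respond to stimulation and to cell dissociation, 2 rose and 8 fell (5 and 13 adjusted over the list alone; camera adjusted p = 0.157, and 0.00280 to 0.318 under 15 other settings, 2 of which called it lower). Fosb and Fos fell, Fos by 1.42 on the log2 scale, while the heat shock chaperone Hsp90aa1 went from 277 ± 19.7 to 822 ± 126 FPKM (SD, n = 3), with a log2 change of 1.56 ± 0.14 (adjusted p = 0.00418). Jun had a change of -1.13 ± 0.30 (adjusted p = 0.0558). The members that fell numbered 1 without control 2 or control 3, 5 without K10-spastin 1 and 3 without K10-spastin 2 or with no filter. They numbered 9 without control 1, where the list was called lower, as it was without control 1 and K10-spastin 1 together.

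Of 14 markers of basal keratinocytes, 3 fell (8 adjusted over the list alone; camera adjusted p = 0.0150, adjusted p = 0.659 with an estimated correlation, and 2.99e-04 to 0.232 under 15 other settings, 2 of which ended the call). Besides Krt15, Itgb1 changed by -1.27 ± 0.24 and Dst by -1.19 ± 0.24. The abundant basal keratins Krt5 and Krt14 had changes of -0.78 ± 0.38 and 0.07 ± 0.53 (adjusted p = 0.202 and 0.939). Of 10 hair follicle genes, 6 fell (1 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.0197, adjusted p = 0.655 with an estimated correlation, and 0.00452 to 0.168 under 15 other settings, 1 of which ended the call). Gli1 and Ptch1, both hedgehog targets, changed by -1.69 ± 0.30 and -1.21 ± 0.25, and Sox9 had a change of 1.55 ± 0.56 (adjusted p = 0.110). No basal marker fell without any one of the controls, and 6 fell without K10-spastin 2. The hair follicle genes that fell numbered 1, 1 and 0 without control 1, 2 and 3 in turn, and 2 without K10-spastin 1 or K10-spastin 2. With no filter no member of these 2 lists fell, and no hair follicle gene fell without control 1 and K10-spastin 1 together.

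Markers of cells outside the epidermis were read in the same libraries, beside the lists that fell. Of 7 tested dermal fibroblast genes, 1 fell (5 adjusted over the list alone; camera adjusted p = 0.0733, and 0.00130 to 0.710 under 15 other settings, 4 of which called it lower). Dcn went from 8.46 ± 5.58 to 1.45 ± 0.942 FPKM (SD, n = 3), with a log2 change of -1.88 ± 0.46 (adjusted p = 0.0456), and Col1a1 stood at 0.724, 8.42 and 13.3 FPKM in controls 1 to 3 and at 0.0324, 0.0287 and 0.0647 FPKM in K10-spastin 1 to 3 (adjusted p = 0.0599). Postn, which is also on the matrix list, had a change of -1.10 ± 0.31 (adjusted p = 0.0626). None of 4 erythroid genes passed by limma, with 2 lower at an unadjusted p under 0.05 (camera adjusted p = 0.10, and 3.85e-04 to 0.231 under 15 other settings, 3 of which called it lower). Hba-a1 stood at 3.65, 30.7 and 142 FPKM in controls 1 to 3 and at 9.75, 3.08 and 2.03 FPKM in K10-spastin 1 to 3. Of 4 skeletal muscle genes, 1 fell, also adjusted over the list alone (camera adjusted p = 0.260), and this was Tnni2, with a change of -1.53 ± 0.17. Of 3 Schwann and neural genes, 1 rose, also adjusted over the list alone (camera adjusted p = 0.220), and this was Tubb3, a tubulin, with a change of 2.88 ± 0.67. None of 3 melanocyte genes passed by limma, including at an unadjusted p under 0.05 (camera adjusted p = 0.654), and Pmel had a change of -0.46 ± 0.69 (adjusted p = 0.689). The melanocyte list median against the control mean was -1.46, 1.19 and -1.05 in K10-spastin 1 to 3, and -0.62, 0.01 and 0.65 in controls 1 to 3. Of 8 genes of the periderm, the outermost embryonic layer, 1 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.822, and 0.0384 to 0.969 under 15 other settings, 1 of which called it lower). These were Grhl3, at 0.82 ± 0.21, and Krt13, at -2.81 ± 0.62. Dcn was not called without any one of the 6 libraries (adjusted p up to 0.124). The fibroblast genes that fell numbered 3 without control 1 and 0 without control 2, control 3, K10-spastin 2 or K10-spastin 3, and no Schwann gene rose under median-of-ratios scaling or without any one of the controls or K10-spastin 2. Under quantile normalization 2 fibroblast genes fell. Without control 1, 3 erythroid genes fell, and the fibroblast and erythroid lists were each called lower without control 1, without control 1 and K10-spastin 1 together, and with array weights, and the fibroblast list also with no filter. Neither Grhl3 nor Krt13 was called without any one of the controls, K10-spastin 1 or K10-spastin 2 (adjusted p up to 0.157 and 0.114), and no periderm gene rose under median-of-ratios or quantile scaling. Of 17 other settings, 14 ended the call of Grhl3, the other pseudocounts and filters among them. The periderm genes that fell numbered 2 without control 1 and 0 without control 2, control 3, K10-spastin 1 or K10-spastin 2. The immune, endothelial and Merkel cell lists had fewer than 3 tested genes, and no immune gene had a mean above 0.474 FPKM over the 6 libraries. That mean hides a difference between libraries. The macrophage genes C1qb and C1qa, chosen after their values were seen, stood at 1.74 and 1.62 FPKM in K10-spastin 2. In any other library they stood at no more than 0.611 and 0.360 FPKM. None of 5 sex-linked genes passed by limma, including at an unadjusted p under 0.05 (camera adjusted p = 0.421).

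**Figure D3:**
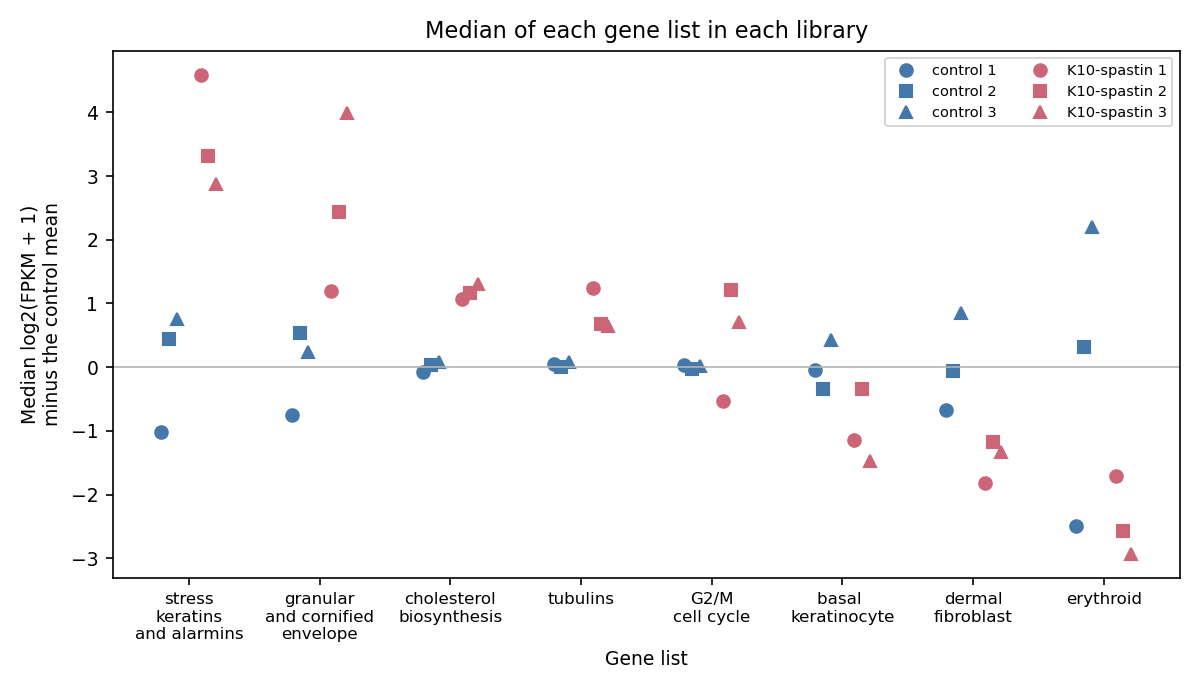
The median of log2(FPKM + 1) of 8 gene lists in each of the 3 control (blue) and 3 K10-spastin (red) libraries, minus the control mean of each gene. The cholesterol list lies at 1.06, 1.16 and 1.31 in K10-spastin 1 to 3, while the G2/M list lies at -0.53 in K10-spastin 1 and at 1.22 and 0.72 in the others.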

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

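Leaving out control 1 and K10-spastin 1 together, the gene families and the tests of other splits were chosen after the data were seen, and the other settings before. In the all-gene comparison 569 genes were higher and 653 lower, and 46.6% of calls were higher. Counts were 319 and 348 with no filter, over 20977 genes, which adds tests of low genes, and 471 and 414 with a filter at 5 FPKM, over 8243 genes. A fold of at least 2 left 394 and 423 by its own construction. Array weights gave 1535 and 1771, and the cause was not tested. Pseudocounts of 0.1 and 0.5 gave 554 and 575, and 568 and 622. Median-of-ratios scaling gave 721 and 757 and quantile normalization 607 and 888, while limma without a trend gave 507 and 677 and with robust variances 572 and 662. Without 1 library the higher genes ranged from 113 to 691 and the lower genes from 32 to 701, with fewer libraries in each fit. Of the calls, 67.0% were higher without control 2 and 77.9% without control 3. Without control 1 and K10-spastin 1 together there were 634 and 625, and the median change of all tested genes moved by 0.12. A count-based test, planned for a table of counts, was not run since the table holds FPKM.

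With the replicate block, 274 genes were higher and 218 lower, and Krt10 was not called. Libraries with the same number had correlated deviations of -0.13, -0.38 and -0.05, and 0 of 6 libraries correlated best with their own number, so the numbers were not taken to pair the libraries. Of the gene lists, 9 were higher and 4 lower. An estimated correlation called 0 and 0, fry called 2 and 0, and the block called 12 lists higher and 7 lower, the fibroblast, erythroid and immediate-early lists among the lower. The differentiation factor, junction and cytokine lists were among the higher. Without 1 library, the lists higher ranged from 8 to 14 and the lists lower from 3 to 8. Without control 1 and K10-spastin 1 together there were 10 and 9. Why these counts moved was not tested, except that fry does not compare a list with other genes.

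Of the list results under other settings, 574 kept their direction and side of the threshold, 37 lost and 43 gained a call, and 28 reversed, none of them for a list called in the report. The adjusted p of lists that reversed was 0.729 for the desmosome list with array weights and 0.808 with quantile normalization, and 0.490 for YAP and TAZ targets with array weights and 0.745 with fry. With no filter it was 0.895 for melanocyte, 0.917 for periderm, 0.389 for Schwann and neural and 0.809 for spinous genes. The periderm list gave 0.582 with a filter at 5 FPKM and nuclear oxidative phosphorylation 0.808 with quantile normalization. With libraries left out, adjusted p ranged from 0.302 to 0.825 for the desmosome list, 0.00965 to 0.904 for cytokines, 0.0979 to 0.994 for keratinocyte integrins, 0.210 to 0.999 for melanocyte, 0.0384 to 0.969 for periderm, 0.00190 to 0.868 for S phase, 0.226 to 0.735 for sex-linked, 0.314 to 0.979 for spinous, 0.0157 to 0.819 for SRF and MRTF targets and 0.209 to 0.973 for YAP and TAZ targets. The cause was not tested.

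Of the results of named genes under other settings, 1895 kept their direction and side of the threshold, 282 lost and 50 gained a call, and 39 reversed, each in a gene not called in the report. Log2 changes with array weights were -0.0011 for Actg1, -0.015 for Cdh1, -0.10 for Cdh3, -0.12 for Cdkn1a, 0.0028 for Erbb2, -0.63 for Krt14 and 0.021 for Pcna. Median-of-ratios scaling gave 0.10 for Erbb2, 0.071 for Klf4 and 0.058 for Perp. Quantile normalization gave -0.0047 for Jup, 0.049 for Klf4, -0.017 for Krt14, -0.24 for mt-Co1 and -0.12 for Taldo1. With libraries left out, Actb ranged from -0.42 to 0.036, Actg1 from -0.027 to 0.52, Cdkn1a from -0.20 to 0.22, Ddx3y from -1.84 to 0.44, Erbb2 from -0.13 to 0.13, Klf4 from -0.21 to 0.10, Krt14 from -0.43 to 0.66, Lor from -0.087 to 1.11, Nfkbia from -0.90 to 0.015, Pcna from -0.38 to 0.12, Perp from -0.23 to 0.076, Pmel from -1.29 to 0.033 and Taldo1 from -0.0061 to 0.059. The cause was not tested. Depths of 16.0 to 22.5 M (mega) fragments put 3 fragments in a transcript of 1 kb at 0.133 to 0.187 FPKM, so genes below that level were not detectable with confidence.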

Other observations

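The tests of other splits of the libraries, of genomic DNA as the whole cause and of basal cell share were chosen after the values were seen, as were the gene families below. The patterns in long non-coding RNA, Rpl26 and glucocorticoid receptor targets were also noticed in these data. For their other tests, only the bounds were set before the test results were seen. Families were formed by the letters that open a gene symbol, and 191 families with at least 8 tested genes were each tested for rises and for falls by Fisher's exact test, 382 tests in all with Benjamini-Hochberg adjustment. This test takes genes as independent. Members of a family were measured in the same 6 libraries and can vary together, so its p-values may be too small. Of 14 Sprr genes, 10 rose (adjusted p = 3.78e-08), and of 9 kallikreins of the Klk family, 7 rose (adjusted p = 5.74e-06). Of 14 Psmd genes, which encode the regulatory particle of the proteasome, 6 rose (adjusted p = 0.00361), with a median of 0.43. Under quantile scaling 1 of the Psmd genes rose. Of 12 Serpinb protease inhibitors, 5 rose (adjusted p = 0.0158), and of 34 Il genes, interleukins and their receptors, 8 rose (adjusted p = 0.0163) and 4 fell. Of 18 collagens, 8 fell (adjusted p = 4.61e-04) and 1 rose, with a median of -1.21. Each median kept its sign under median-of-ratios and quantile scaling. No Psmd gene rose without any one of the controls, and 1 rose without K10-spastin 2 or K10-spastin 3. No Il gene fell without any one of the controls, and 2 fell without K10-spastin 1 or K10-spastin 2. The Il genes that rose numbered 2, 1 and 1 without control 1, 2 and 3 in turn, the Serpinb genes 3, 2 and 0, and the collagens that fell 4, 2 and 0. Without control 3, 4 Klk genes rose. Without K10-spastin 1 or K10-spastin 3, 4 collagens fell. Some members of the Sprr, Klk and Il families are also on the fixed lists, and the fibroblast collagen Col1a1 was itself highest in controls 2 and 3.

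The alarmin Il33, chosen after its values were seen, went from 0.890 ± 0.772 to 111 ± 125 FPKM (SD, n = 3), with a log2 change of 5.22 ± 0.89 (adjusted p = 0.0171). It was not called without any one of the controls (limma adjusted p up to 0.0630). Among collagens, also chosen after their values were seen, Col7a1, of the anchoring fibrils below the epidermis, went from 59.3 ± 23.1 to 16.0 ± 5.09 FPKM (SD, n = 3), with a log2 change of -1.78 ± 0.35 (adjusted p = 0.0243), and Col4a5, of the basement membrane, went from 17.1 ± 1.28 to 5.44 ± 2.59 FPKM (SD, n = 3), with a log2 change of -1.59 ± 0.33 (adjusted p = 0.0284). Col7a1 was not called without control 1, control 3 or K10-spastin 1 (limma adjusted p up to 0.0976). Col4a5 was not called without any one of the controls (up to 0.111). Controls 2 and 3 held both Xist and Y-linked transcripts, and the other 4 libraries held 1 kind or the other above 0.1 FPKM. Transcripts of both sexes at these levels argue against a single embryo in control 2 or in control 3. The number of embryos per library is not given in the sources used here, so n counts RNA samples and the SD is the spread between them. Sex make-up differed between the libraries, and no sex term was fitted. Xist, expressed in female cells, stood at 0.0285, 64.2 and 63.3 FPKM in controls 1 to 3 and at 0.00923, 0.0573 and 48.2 FPKM in K10-spastin 1 to 3. The Y-linked Ddx3y stood at 20.8, 11.4 and 13.6 FPKM in the controls and at 23.0, 18.1 and 0.0203 FPKM in K10-spastin.

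The split of the 6 libraries that follows the labels called 1222 genes and the highest of the other splits called 1. It was the only split, 1 of 10, with as many genes. For gene lists, the split that follows the labels called 13 lists and the highest of the others called 22, and 7 of 10 splits called as many. With 10 splits no share below 0.05 can be had. Each of the other splits had libraries of both groups on both sides. They keep part of the group difference and add the rest to the spread, so neither their gene counts nor their list counts measure chance.

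Long non-coding RNA genes were lower in K10-spastin as a class: of 257 tested, 41 fell and 5 rose, and the median change was -0.50. A low expression level was argued against, since 0% of 10000 lists of protein-coding genes matched on mean FPKM had a median as low, their medians running from -0.33 to -0.06. For reads from the gene on the other strand, the overlapping protein-coding genes of 75 antisense RNAs had a median of -0.045, against -0.46 for the RNAs. This argues against reads that follow the FPKM of the overlapping gene. Overlap was taken over gene spans, introns included, so reads from introns of that gene were not tested. Genomic DNA in the control libraries was tested by receptor genes that skin does not express, and their summed FPKM was 1.71 times higher in control, which fell between the bounds set beforehand and decides nothing. As the whole cause it was argued against by its level, 0.00118 FPKM per receptor gene in control against a median fall of 1.12 FPKM, so that a lower share of nuclear RNA or an effect of genotype on these transcripts may remain, neither of them tested, and the members that fell numbered 25, 6 and 2 without control 1, 2 and 3 in turn and 14 without K10-spastin 2.

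The list of basal keratinocyte markers was called lower by camera (adjusted p = 0.0150) but not with an estimated correlation (adjusted p = 0.659), and 3 of its 14 markers fell, none of them without any one of the controls. The sort was for fluorescence driven by the keratin 10 promoter, a gate that would remove most basal cells, and a smaller share of any that remained would lower these markers together and raise none. Of 14 tested, 2 departed from the list's own mean change, Krt15 by -2.13 ± 0.57 (adjusted p = 0.0406) and Cdh3, chosen after its values were seen, by 1.27 ± 0.26 (adjusted p = 0.0169), and none was called higher. Expression of a marker outside basal cells dilutes its fall, so unequal falls do not exclude a smaller share of basal cells in the sort. That explanation and a fall within each cell cannot be told apart here, since no library holds basal cells alone.

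Rpl26 fell further than the listed ribosomal protein genes and was chosen after its values were seen. It stood at 409, 397 and 567 FPKM in controls 1 to 3 and at 85.7, 108 and 100.4 FPKM in K10-spastin 1 to 3. Gm15772, also chosen after its values were seen, a processed pseudogene 99.5% identical over 438 bases, stood at 234, 233 and 101 FPKM in control and at 337, 447 and 369 FPKM in K10-spastin. The sum of Rpl26 and its near-identical copies differed by -0.43, against a mean of -0.32 for the listed ribosomal protein genes. Reads shared with near-identical copies may therefore account for the difference between Rpl26 and the others, though what moved the split between the copies was not tested.

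A further hypothesis was that lower glucocorticoid receptor target expression in K10-spastin may run through the genes that fell. Of 9 tested targets held out from the genes that gave the idea, 3 were called lower and 1 higher, with a median of -0.73. That lay between the bounds set beforehand, so the hypothesis stays undecided. Single libraries move it: 2 were called lower without control 2 or control 3, which is under the lower bound, 3 without control 1, and 4 without K10-spastin 3. None was called higher without any one of the controls or K10-spastin 2, and 2 were without K10-spastin 1. Those called lower, named after their values were seen, were Mt1, at -1.77 ± 0.39, Per1, at -1.26 ± 0.16, and Hif3a, at -1.72 ± 0.23, and Map3k6 was higher, at 0.76 ± 0.15.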
